A study of Mus musculus with 61 samples.

How the data were processed

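The series holds 61 Affymetrix arrays of mouse CD4 T cells. Per the labels' protocols, naive cells were cultured with an antibody to CD3 and a second one, both at 1 µg/ml, the second written as an antibody to CD8, and 6 µg of total RNA extracted with Trizol was made into biotin-labelled cRNA. The same protocol text, with IL-27 at 25 ng/ml, is attached to every sample, control arrays included, so the arm, time and array type of each array were taken from its title and not from the protocol. The titles give times as bare numbers, read here as hours, and some end in a suffix d whose meaning is not given in the sources used here. GFPP and GFPN, the names of 1 array each, are not explained there either.

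The deposited tables, one per array type, hold an intensity on a linear scale for each of 22626 probe sets and each array. MAS5 is the only tool the submitters' processing notes name, without a version. Scaling, target and background settings of the authors are not given in the sources used here. Quartiles and medians of the arrays of one type were alike (medians 28.0 to 36.6 on HT_MG-430A, 70.7 to 78.9 on Mouse430A_2), so the deposited intensities were taken as normalized by the authors, separately for each array type, and no further normalization was applied. The array types were therefore tested apart. No array pair had identical values. Gene names came from the platform annotation tables of both array types, which list the same probe sets, with symbols updated through gene identifiers: 20173 probe sets had 1 gene, 942 several and 1511 none, and those with several or none were left out. Among those with 1 gene, 17356 had the same name in both tables, 110 differed and took the name of the HT_MG-430A table, 35 were named only there and 2672 only in the Mouse430A_2 table. They gave 12291 genes, and list members without a named probe set were not analysed here. A gene was represented by its brightest probe set over the arrays of one type. Of the genes named for their size in a window, 21 had 2 or more probe sets, none with a difference of the opposite sign, but sizes disagreed, as for Scd2, Sox4, Rtp4, Igfbp7 and Mt1 (0.07 to 2.45 late). A comparison of probe sets at the 3' and 5' ends of housekeeping transcripts, planned as a check of RNA quality, was not run, since no control probe sets were in the tables used here.

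Values were tested as log2(intensity + 32) with limma 3.58.1 in R 4.3.3. A gene was kept if it lay above its own array's median on at least 5 arrays of the fit. For GFPP against GFPN a gene was kept if it lay above the array's median on either array, and with 1 time of Mouse430A_2 left out, on at least 3 of the 4 arrays. The groups, models, gene lists, named-gene rule and alternatives were fixed before the data were examined, except where stated. For the IL-27 effect, 1 model over the 52 HT_MG-430A arrays had time as a factor and an IL27 coefficient for each window: early (0.5 to 4 h, 4 times, 5 arrays per arm), middle (8 to 20 h, 6 times, 9 arrays per arm) and late (25 to 72 h, 8 times, 12 arrays per arm). Its spread includes the variation of the effect between times of a window. The change of the effect was the late minus early contrast. Single times were tested with a mean for each arm and time, and the spread came from the times with 2 arrays per arm. The 26 control arrays were compared between windows, and the 6 Mouse430A_2 arrays with a matched arm were tested with time as a factor, which leaves 2 residual degrees of freedom. Spreads were moderated by eBayes with an intensity trend, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of one comparison, and again with an estimated correlation; member counts use the adjustment over all genes tested, and a second count was adjusted over the list alone. Some lists share members, such as Irf1, Batf, Il21 and Gzmb. For each called list the median, mean and direction of the test had one sign. They did not in some lists that were not called, early for Treg, cell cycle, glycolysis, unfolded protein and MHC class II genes, middle for co-inhibitory receptors, and late for co-inhibitory receptors, Th17 and activation genes. The same held late minus early for STAT3 and Th17 genes, in control cells for Tr1, Th2, Th17 and cytotoxic genes, and on Mouse430A_2 for activation genes. Percentiles of lists on the GFPP and GFPN arrays came from 10000 random lists of the same size, matched in 20 bins of mean expression.

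The text names, per window, the 8 genes with the largest difference each way among called genes with the sign of the effect at 80% or more of the window's times. For the control comparison it names the 8 largest each way among called genes, for Mouse430A_2 the 5 largest each way among called genes or none, and for GFPP against GFPN the 10 largest ratios each way. It adds 2 to 4 members per list with the smallest adjusted p, and every measured Tr1 regulator. Other genes were named after their values were seen, as single members of lists or as examples at single times. Arrangements tried as alternatives were pseudocounts of 1 and 100, quantile normalization, no filter or a stricter one, the mean of all probe sets and eBayes without trend. Further ones were a block for the suffix d, the mean of single-time contrasts, leaving out arrays of suffix d or each time in turn and, for lists, fry and an estimated correlation. Models without the 12 h control array, list tests without the 48 h arrays, and names from each array type's own annotation table alone were added after the data were seen.

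The models were tested on simulated intensities for the real genes, with 67, 67 and 66 genes changed by 0.5, 1 and 2 on the log2 scale. The early window recovered 67.2%, 97.0% and 98.5% of them over 7696 genes, the middle window 88.1%, 97.0% and 100% (7691 genes), the late window 97.0%, 100% and 100% (7697 genes), and late minus early 65.7%, 95.5% and 100% (7697 genes). A time with 1 array per arm, 36 h, recovered 10.4%, 62.7% and 97.0% (7682 genes), and 72 h, with 2, recovered 31.3%, 85.1% and 98.5% (7692 genes). The control comparison recovered 38.8%, 85.1% and 100% (7375 genes) and Mouse430A_2 5.97%, 52.2% and 72.7% (6343 genes). Unchanged genes made up between 2.25% and 6.95% of the calls. The simulated noise was normal and independent between genes and arrays. It held no shift shared by arrays of one suffix and no outlying array, and a simulated change was constant over the times compared. These rates may therefore not carry over to the real arrays. The simulation was rewritten after earlier forms, which left real signals in place, had given more false calls. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.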

Results

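Transcript levels were measured on 61 Affymetrix arrays of naive CD4 T cells from C57BL/6 mice, stimulated in culture through CD3 in a control arm (ctrl) or with IL-27, a cytokine of the IL-12 family (IL27). By its title, the series asks which transcriptional program IL-27 sets up as such cells become type 1 regulatory (Tr1) cells, a Foxp3-negative T cell type that makes IL-10. HT_MG-430A arrays numbered 26 per arm over 18 times from 0.5 to 72 h, with 2 arrays per arm at 8 times and 1 at the other 10. The labels give times without a unit, and hours are assumed throughout. A smaller set of 9 Mouse430A_2 arrays held a control array at 0 h, 1 array per arm at 4, 16 and 48 h, and 1 array each named GFPP and GFPN at 48 h. Array medians lay between 28.0 and 36.6 intensity units on HT_MG-430A and between 70.7 and 78.9 on Mouse430A_2, and the number of arrays limits the precision. Nothing in the labels says that arrays of one arm came from separate cultures or animals, so p-values measure only the spread between these arrays, which may be technical. Differences are IL27 minus ctrl on the log2(intensity + 32) scale, which understates changes of dim genes. The 12 h control array stood apart from the rest: across 6673 genes its highest correlation with any other HT_MG-430A array was 0.8525, against at least 0.974 for the other arrays. Window counts, genes named for their size, Tr1 regulators and middle list members were also looked up in a model fitted without it, a comparison added after the data were seen.

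The early window asks which genes IL-27 changes first. Within these 4 h, interferon-inducible genes were higher with IL-27. Iigp1, an interferon-inducible GTPase, rose from a mean intensity of 585 to 2413, a log2 difference of 2.68 ± 0.45 (SE, 5 arrays per arm). Cxcl10, a chemokine that attracts CXCR3-bearing T cells, rose from 130 to 859 (2.66 ± 0.24, limma adjusted p = 3.4e-09). Gbp10 (2.09 ± 0.35), Rtp4 (2.06 ± 0.29), Ifit1 (2.04 ± 0.28) and Zbp1 (1.94 ± 0.32), all interferon-induced, rose with them, as did the signalling inhibitor Socs1 (1.94 ± 0.28) and Frmd4b (2.02 ± 0.28). The lower genes moved less. Id3, an inhibitor of E-protein transcription factors, fell by 0.89 ± 0.23 (adjusted p = 0.030). Klf3 fell by 0.79 ± 0.19, the desaturase Scd2 by 0.78 ± 0.17 and the adaptor Sit1 by 0.75 ± 0.12. The transcription factors Myb and Sox4 fell by 0.69 ± 0.19 and by 0.64 ± 0.17, the proton channel Hvcn1 by 0.57 ± 0.09 and the co-stimulatory receptor Cd28 by 0.53 ± 0.13. The Scd2 value came from the brightest of 3 probe sets, which ran from -0.78 to -0.04, and with their mean it was -0.32 (adjusted p = 0.13). These 16 genes had the same sign at all 4 times of the window. They were picked for the same sign at 80% or more of the times, which with 4 times means all. In all, 166 of 7163 genes were called (128 higher, 38 lower), and all 46 with a difference of 2-fold or more were higher. The number of lower genes was 13 as a mean of single-time contrasts and 19 with a pseudocount of 1. It was 25 among genes above the median mean value or without 1 h, 59 with a pseudocount of 100, 74 without the 12 h control array and 81 with a block for the title suffix d.

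Among the gene groups of the early window, 25 of the 28 tested interferon response genes rose and none fell (28 higher adjusted over the list alone), with a median difference of 1.25. Rsad2 (0.83 ± 0.08), an antiviral enzyme, Irf7 (1.14 ± 0.15), a transcription factor of the type I interferon response, and the guanylate-binding protein Gbp3 (1.85 ± 0.26) were examples. Camera gave the list an adjusted p of 2.3e-78 (adjusted p = 1.9e-05 with an estimated correlation). STAT3 and SOCS feedback genes gave 6 higher and 1 lower of 16 (7 and 1 adjusted over the list alone; camera adjusted p = 2.2e-10, and 3.5e-05 with an estimated correlation). Socs3 (1.50 ± 0.22), the feedback inhibitor of STAT3 signalling, the IκB-family protein Bcl3 (1.04 ± 0.16) and the STAT target Cish (0.93 ± 0.18) were higher and the transcriptional repressor Bcl6 lower (-0.53). MHC class I and antigen processing genes gave 2 higher of 10 (6 adjusted over the list alone; camera adjusted p = 4.2e-07, and 0.069 with an estimated correlation). These were the immunoproteasome subunit Psmb9 (0.83 ± 0.18) and the proteasome activator Psme1 (0.24 ± 0.07). No other list except the Tr1 list was called at this stage (camera adjusted p from 0.12 to 0.91), though single members moved. Tbx21, which encodes the Th1 regulator T-bet, rose by 1.87 ± 0.32 and Cd274 (PD-L1) by 1.19 ± 0.21. Smaller rises were those of the hexokinase Hk1 (0.84 ± 0.19), of Ikzf4 (0.61 ± 0.16) and of the replication licensing factor Mcm4 (0.39 ± 0.10). Marker lists of B cells, myeloid and dendritic cells and MHC class II had early medians of -0.09, 0.06 and -0.01 and were not called.

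The early calls rested largely on the 2 h arrays. Without that time 9 genes were called, all higher, and of the 16 genes named for their size and the 3 Tr1 regulators called early (Batf, Irf4 and Irf1), Cxcl10, Socs1 and Batf stayed past the threshold and 16 did not. Other list members were not tested this way. Of the 16, the higher ones were Iigp1 at 1.98 (adjusted p = 0.20), Zbp1 at 1.16 (0.28), Gbp10 at 0.81 (0.58), Rtp4 at 1.32 (0.098), Ifit1 at 1.22 (0.088), Frmd4b at 1.23 (0.086), Irf4 at 1.13 (0.10) and Irf1 at 1.03 (0.17). The lower ones were Sit1 at -0.46 (0.10), Hvcn1 at -0.38 (0.11), Klf3 at -0.58 (0.60), and Id3, Scd2, Myb, Sox4 and Cd28 between -0.40 and -0.30 (0.999 for each). Without 1 h, Id3 (-0.93, adjusted p = 0.067), Cd28 (-0.54, 0.064), Myb (-0.72, 0.090), Irf1 (0.83, 0.073) and Irf4 (0.87, 0.065) also missed the threshold. Without 4 h, Myb (-0.75, 0.063) and Sox4 (-0.66, 0.078) did. Without the arrays whose title ends in the suffix d, which the labels do not explain, 57 genes were called (44 higher, 13 lower). Then Irf1 (1.09), Irf4 (1.23), Gbp10 (1.60), Id3 (-0.66), Scd2 (-0.62), Myb (-0.59), Sox4 (-0.52) and Cd28 (-0.41) were not called (adjusted p from 0.059 to 0.36), with fewer arrays in the fit. As a mean of single-time contrasts Cd28, Id3, Klf3, Myb and Sox4, between -0.71 and -0.44, were not called (adjusted p from 0.050 to 0.21). The same held with a pseudocount of 1 for Klf3, Myb and Sox4 (0.051 to 0.097), without the filter on low values for Myb (0.066) and Sox4 (0.050) and with quantile normalization for Id3 (0.051).

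The middle window asks what follows the first response. Between 8 and 20 h, Tbx21 had the largest difference on the log2(intensity + 32) scale, which ranks dim genes low, and went from a mean intensity of 241 to 1840 (log2 difference 2.95 ± 0.24, 9 arrays per arm, adjusted p = 4.7e-11). Egln3, a prolyl hydroxylase that marks HIF subunits for degradation, rose from 33.2 to 426 (2.67 ± 0.19), Tmem35a from 14.1, below every array median, to 258 (2.47 ± 0.20) and the membrane-anchored semaphorin Sema7a by 2.00 ± 0.15. The interferon-inducible GTPases Iigp1 (2.07 ± 0.34), Irgm1 (2.06 ± 0.22), Gbp10 (2.03 ± 0.26) and Gbp2 (1.62 ± 0.23) were higher as well. Tnfsf11, which encodes the TNF-family cytokine RANKL, fell by 2.17 ± 0.20 from 1552 to 341. Lad1 fell by 1.67 ± 0.20, the chemokine Xcl1 by 1.56 ± 0.15 and the death ligand Fasl by 1.43 ± 0.16. Niban1 fell by 1.30 ± 0.17, the activation marker Cd83 by 1.24 ± 0.21, Ms4a4b by 1.17 ± 0.17 and the adaptor Stap1 by 1.15 ± 0.13. Each of these 16 genes stayed called without the 12 h control array. Each had its sign at all 6 times, where the rule for naming them asked for 80% or more. Among 7163 genes, 764 were called (345 higher, 419 lower), 40 higher and 15 lower by 2-fold or more. Without the 12 h control array 582 genes were called, 473 of them shared with the 764. Leaving out 16 h gave 439 calls, leaving out 20 h gave 462, and averaging the contrasts of single times, with the spread taken from duplicated arrays alone, gave 1609. Which direction held more calls depended on the setting, with 930 higher and 679 lower in that mean, 396 and 390 with the mean of all probe sets, 214 and 423 without arrays of suffix d and 421 and 639 with a block for that suffix.

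In the middle window 11 of 28 interferon response genes rose and none fell (14 adjusted over the list alone), at a median of 0.32. The GTPase Igtp (1.47 ± 0.14) and the transcription factors Irf1 (1.34 ± 0.17) and Irf8 (1.53 ± 0.24) were among them. Camera called this list (adjusted p = 1.3e-11), and the adjusted p was 0.11 with an estimated correlation. MHC class I and antigen processing genes rose in 8 of 10 cases (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.4e-10, and 0.018 with an estimated correlation). Among them were Psmb9 (1.16 ± 0.13), the aminopeptidase Erap1 (0.60 ± 0.08) and the peptide transporter Tap2 (1.04 ± 0.14). STAT3 and SOCS feedback genes gave 9 higher of 16 and none lower (9 adjusted over the list alone; camera adjusted p = 1.6e-10, and 7.2e-05 with an estimated correlation). These included Bcl3 (1.09 ± 0.12), Socs3 (1.45 ± 0.17) and the IL-21 receptor Il21r (0.79 ± 0.10). Without the 12 h control array the member counts of these 3 lists were the same.

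In the middle window 6 further lists lost their call when the correlation was estimated. Of 9 Th2 genes, 1 rose and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.032, with an estimated correlation 0.067, with quantile normalization 0.060, and among genes above the median mean value 0.44 at a median of 0.03). The falls were led by Gata3 (-0.89 ± 0.10), the Th2 master regulator, and the chemokine Ccl1 (-1.06 ± 0.12). Of 23 T-cell activation genes, 6 rose and 1 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.036, with an estimated correlation 0.36, with fry 0.057, with the mean of all probe sets 0.064 and without the 12 h control array 0.052). Jun stood at 1.09 ± 0.17 and Tnf at 0.83 ± 0.14. Glycolysis and hypoxia genes gave 4 higher of 17 (5 adjusted over the list alone; camera adjusted p = 0.0057, and 0.36 with an estimated correlation). Among them were Hif1a (0.54 ± 0.07) and Pfkp (0.57 ± 0.08). Cholesterol biosynthesis genes gave 5 lower of 16 (7 adjusted over the list alone; camera adjusted p = 0.016, and 0.36 with an estimated correlation). Idi1 stood at -0.41 ± 0.09 and Sqle at -0.31 ± 0.07. Unfolded protein and amino acid response genes gave 3 higher of 19 (3 adjusted over the list alone; camera adjusted p = 0.032, and 0.36 with an estimated correlation). They were Sesn2, Slc3a2 and Hspa5. Of 33 cell cycle genes 1, Tk1 (-0.51 ± 0.15), was lower (1 adjusted over the list alone; camera adjusted p = 0.034, with an estimated correlation 0.62, and from 0.055 to 0.23 with fry, a pseudocount of 100, quantile normalization or no filter). Without the 12 h control array the member counts were 2 lower for Th2 genes, 5 higher and 2 lower for activation, 4 lower for cholesterol and 2 lower for cell cycle genes, and the same for glycolysis genes. Of the unfolded protein genes only Sesn2 then stayed called (Slc3a2 at 0.21, adjusted p = 0.064; Hspa5 at 0.16, 0.11). The remaining lists were not called (camera adjusted p from 0.063 to 0.75). Markers of other cells moved singly. The CD8 chain Cd8b1 changed by -0.58 ± 0.11, the immunoglobulin heavy chain Ighm changed by -0.65 ± 0.17, Car2 by -0.34 ± 0.10 (not called without the 12 h control array, -0.26, adjusted p = 0.12) and Mpeg1 by 0.18 ± 0.05.

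The late window covers the times by which a lasting program would be in place. From 25 to 72 h, Plac8 and the cytokine gene Il21 showed the largest differences on the log2(intensity + 32) scale. Plac8 went from a mean intensity of 41.4 to 1192 (log2 difference 3.61 ± 0.23, 12 arrays per arm, adjusted p = 5.6e-15). Il21, whose product signals through STAT3, went from 22.9 to 504 (3.14 ± 0.19, adjusted p = 3.1e-15). Ctla2a (2.85 ± 0.20), the metallothioneins Mt2 (2.48 ± 0.23) and Mt1 (2.45 ± 0.20), P-selectin (Selp, 2.14 ± 0.18), Serpinb5 (10.3 to 302; 2.06 ± 0.29) and the stress-induced Gadd45g (1.94 ± 0.16) rose too. The control means of Il21 and Serpinb5 lay below every array median, so their rank by ratio was not measured. Tnfsf11 fell by 3.07 ± 0.18, from 1274 to 123, Lad1 by 3.06 ± 0.17 and Cd83 by 2.73 ± 0.18. Ifi205 (-2.33 ± 0.20), the T-box factor Eomes (-2.25 ± 0.16), Csf2 (-2.06 ± 0.24), which encodes the cytokine GM-CSF, Fasl (-1.85 ± 0.14) and Igfbp7 (-1.78 ± 0.16) were also lower. The 16 genes were picked for the same sign at 80% or more of the times. They had it at all 8, except Mt1 at 7 of 8. Igfbp7 depended on its probe set: its 3 probe sets ran from -1.78 to -0.02, and with a pseudocount of 1, which makes another of them the brightest, the difference was -0.07 (adjusted p = 0.74). In total 1325 of 7163 genes were called (625 higher, 700 lower), 47 higher and 39 lower by 2-fold or more. The count was 883 without 54 h.

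**Figure D1:**
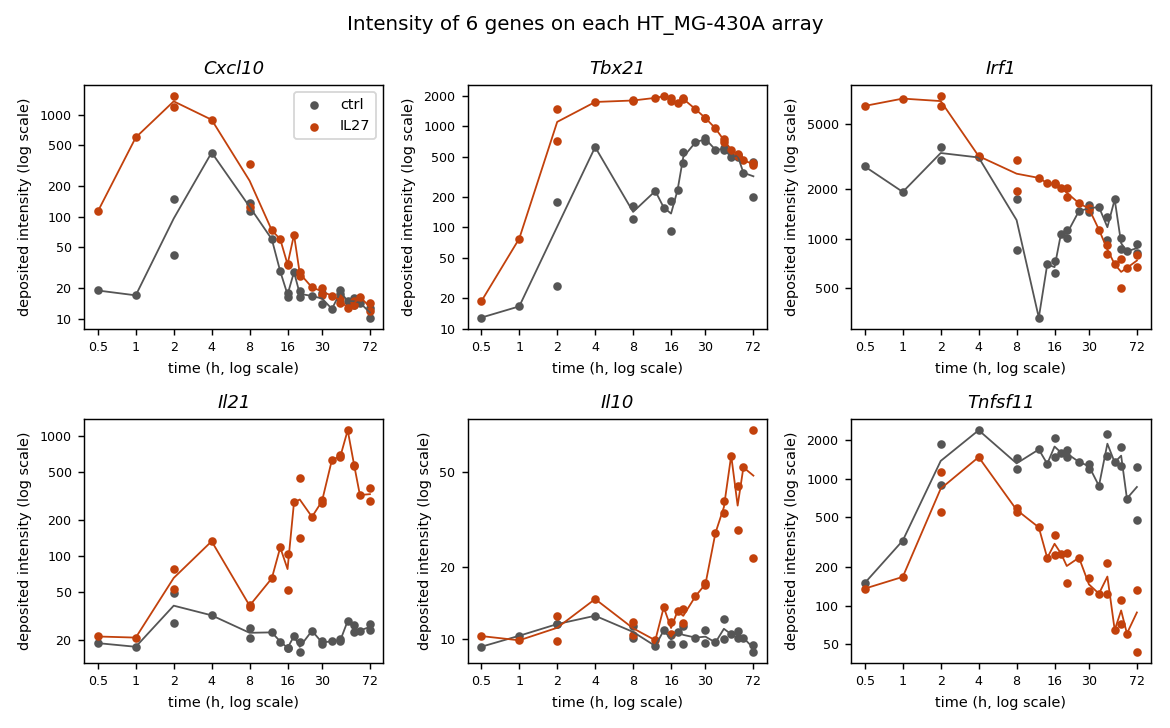
Deposited intensity (log scale) of 6 genes on each HT_MG-430A array against time in hours (log scale), with points for single arrays and lines through the mean of each arm, ctrl in grey and IL27 in orange. Cxcl10 and Irf1 differed between arms at the earliest times, Irf1 also from 8 to 20 h, Tbx21 most from 2 to 20 h, and Il21, Il10 and Tnfsf11 most in the late window, where mean Il10 was 10.1 in ctrl and 35.7 in IL27.

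Cytotoxic genes were the group with the highest late median (1.20): of 7 tested, 6 rose and 1 fell (the same counts adjusted over the list alone). The cathepsin Ctsw rose by 1.63 ± 0.19, Nkg7, a granule membrane protein, by 1.62 ± 0.19 and the pore-forming Prf1 by 1.20 ± 0.17, whereas Fasl fell by 1.85. Camera gave an adjusted p of 8.4e-05 (0.0012 with an estimated correlation). Beside this group, the CD8 marker Cd8b1 changed by -0.62 ± 0.09, from 168 to 95.2. The other CD8 marker, Cd8a (11.8 in ctrl and 11.6 in IL27), and the genes of the NK marker list did not pass the filter on low values. Klrd1, a cytotoxic list member that encodes an NK receptor chain, rose by 0.63 ± 0.16 (adjusted p = 0.0030), from 13.6 to 58.7. Without that filter the NK receptor gene Klrc1 differed by 0.17 ± 0.06 (adjusted p = 0.043), from 17.6 to 25.0. Over the 3 windows, 11 of 21 list calls hold with an estimated correlation: Tr1 and STAT3 genes in each window, interferon genes early, MHC class I genes in the middle window, and cytotoxic, Treg and cholesterol genes late. STAT3 and SOCS feedback genes gave 9 higher and 2 lower of 16 (the same adjusted over the list alone; camera adjusted p = 2.6e-06, and 0.0013 with an estimated correlation). Socs3 stood at 1.85 ± 0.14 and Bcl3 at 1.37 ± 0.10. Treg genes fell in 5 of 11 cases and rose in none (6 lower adjusted over the list alone; camera adjusted p = 0.00026, and 0.010 with an estimated correlation). Among them were the semaphorin receptor Nrp1 (-1.11 ± 0.07), Izumo1r (-0.67 ± 0.10), which encodes folate receptor 4, and Gpr83 (-0.69 ± 0.13). Cholesterol biosynthesis genes fell in 11 of 16 cases (12 adjusted over the list alone; median -0.38; camera adjusted p = 2.9e-09, and 0.018 with an estimated correlation). Examples are Hsd17b7 (-0.66 ± 0.07), Idi1 (-0.66 ± 0.08) and Cyp51 (-0.48 ± 0.07).

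Glycolysis and hypoxia genes rose in 11 of 17 cases late (12 adjusted over the list alone; median 0.33; camera adjusted p = 1.9e-07, and 0.052 with an estimated correlation). Among them were Egln3 (1.41 ± 0.17), Hif1a (0.45 ± 0.06), the oxygen-regulated transcription factor, and Pfkp (0.37 ± 0.07). At 48 h the list's median was -0.23, where the control mean stood at 11.37 (log2) against 10.34 at 42 h and 10.52 at 54 h. The 48 h control array had the lowest correlation with its nearest array (0.974) after the 12 h control. Yet its deviations from neighbouring control arrays were the most alike of all control arrays between the 2 brightest probe sets of a gene. That correlation was 0.856, against 0.056 for the 12 h control, which speaks against a fault of measurement on the 48 h array. It cannot show whether the sample itself was like its neighbours. Without the 48 h arrays, left out after the data were seen, the list's late median was 0.40 (camera adjusted p = 6.5e-10, and 0.0063 with an estimated correlation). Unfolded protein and amino acid response genes gave 4 higher and 1 lower of 19 (the same adjusted over the list alone; camera adjusted p = 0.0024, and 0.093 with an estimated correlation). Trib3 stood at 0.59 ± 0.09 and Ddit3 at 0.71 ± 0.11. Interferon response genes were not called as a list (median -0.10, camera adjusted p = 0.25). Gbp2 (0.71 ± 0.20) and Gbp3 (0.73 ± 0.17) were higher, and Ifih1 (-1.04 ± 0.12), Isg20, Ifi47 and Irf9 lower. MHC class I genes gave 3 lower of 10 (camera adjusted p = 0.25). T helper lists went both ways. Th1 genes gave 3 up and 3 down of 14 (0.25), with Il12rb2, Hlx and Nkg7 higher and Eomes, Fasl and Stat4 lower. Th2 genes gave 2 up and 4 down of 9 (0.067), with Gata3 at -1.35 ± 0.09. Th17 genes gave 1 up and 1 down of 4 (0.67), with the chemokine receptor Ccr6 at -1.65 ± 0.11. Co-inhibitory and co-stimulatory receptors (2 up, 2 down of 12; 0.65), naive and memory genes (1 up, 2 down of 12; 0.44), T-cell activation genes (3 up, 3 down of 23; 0.86) and cell cycle genes (2 down of 33; 0.079) were not called either. Lists of myeloid and dendritic cells (3 down of 8; 0.15), MHC class II (1 up, 2 down of 5; 0.067) and B cells (no call among 4; 0.67) were not called. Adjusted over the list alone, the counts were 4 lower for MHC class I, 6 up and 3 down for Th1, 2 and 5 for Th2, 2 and 3 for co-inhibitory and co-stimulatory receptors and 1 and 3 for MHC class II genes, and the same for the others. Of the markers of other cells, the cathepsin Ctss changed by -0.83 ± 0.10, the invariant chain Cd74 by -1.10 ± 0.13, H2-DMa by -0.56 ± 0.09 and H2-Ab1 by 0.69 ± 0.17, and the erythroid marker Car2 by -0.57 ± 0.09.

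**Figure D2:**
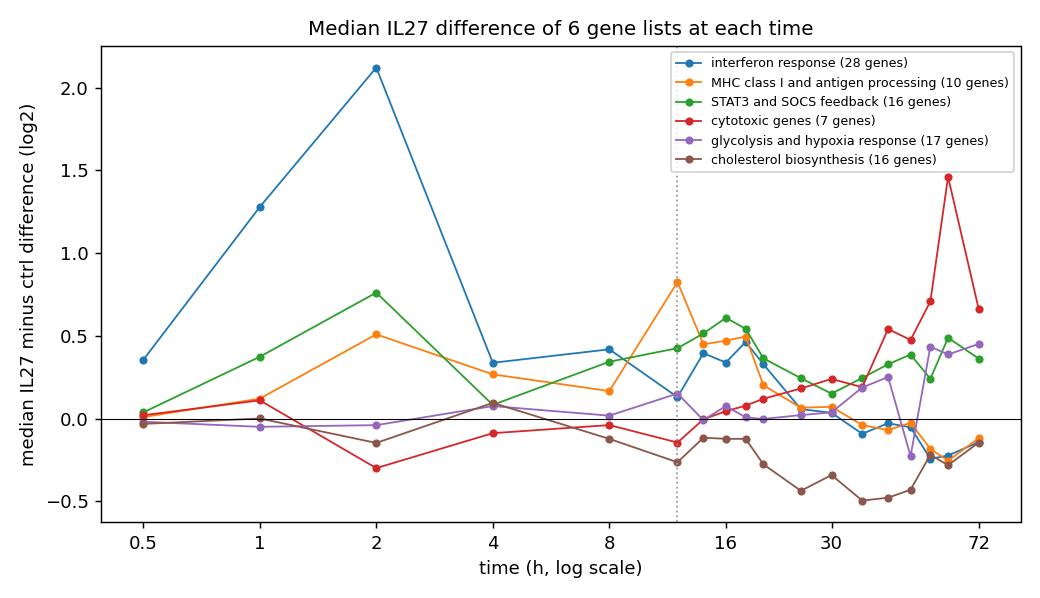
Median IL27 minus ctrl difference (log2) of 6 gene lists at each HT_MG-430A time in hours (log scale), each line one list with its number of genes, the dotted line marking 12 h, where the control array stood apart. The interferon list has its highest median at 2 h and lies near or below 0 from 25 h, while the cytotoxic list is highest at 60 h, with window medians of 1.25 early and -0.10 late for the former and 1.20 late for the latter.

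For the list of Tr1 and IL-10 regulators, 22 genes of which 18 were tested, calls are given by window, and early and middle differences were not tested against each other. Besides regulators, the list holds Il10 itself, the granzyme gene Gzmb and receptors such as Lag3, Icos and Il12rb2. Throughout the text, Tr1 regulators means all members of this list. In the early window the AP-1 factor Batf (1.63 ± 0.17, adjusted p = 7.0e-08), Irf4 (1.13 ± 0.23) and Irf1 (1.04 ± 0.22) rose. That made 3 of 18 (5 adjusted over the list alone; camera adjusted p = 7.1e-06, and 0.00014 with an estimated correlation). The other members ran from Rora at -0.26 to Prdm1 at 0.82 ± 0.31 (adjusted p = 0.23). Il10 stood at 0.01, Ahr at 0.45, Nfil3 at 0.07, Egr2 at -0.03, Ets1 at -0.17, Ets2 at 0.18, Bhlhe40 at -0.06 and Stat3 at 0.49, with Il21 at 0.50, Icos at -0.05, Lag3 at 0.04, Gzmb at 0.20 and Il12rb2 at 0.02. In the middle window 10 rose and 1 fell (11 and 2 adjusted over the list alone; camera adjusted p = 1.5e-06, and 8.5e-05 with an estimated correlation). Il21 (1.44 ± 0.22), Irf1 (1.34 ± 0.17), the granzyme gene Gzmb (1.17 ± 0.20), Batf (1.12 ± 0.13) and Stat3 (0.83 ± 0.16) were higher. So were Egr2 (0.74 ± 0.13), Irf4 (0.52 ± 0.17), the ligand-activated factor Ahr (0.45 ± 0.13), Il12rb2 (0.42 ± 0.10) and the inhibitory receptor Lag3 (0.40 ± 0.13). Bhlhe40, a repressor of Il10, was lower (-0.86 ± 0.13). Without the 12 h control array Irf4 (0.28, adjusted p = 0.27) and Lag3 (0.24, 0.20) were no longer called. Irf4 also missed the threshold when any other middle time was left out, though its difference was then 0.54 to 0.61 (adjusted p from 0.059 to 0.082). The same happened to Lag3 without 8, 14 or 16 h (0.40 to 0.41, adjusted p from 0.051 to 0.098). Ahr missed it without 16, 18 or 20 h (0.36 to 0.37, adjusted p from 0.071 to 0.13) and without arrays of suffix d (0.40, 0.17), and Il12rb2 did without 20 h (0.27, 0.11). With the mean of both its probe sets Ahr stood at 0.21 (adjusted p = 0.068). Irf4 was also not called without arrays of suffix d (0.65, adjusted p = 0.10), with quantile normalization (0.054), without the filter on low values (0.073) or without the trend (0.052). Lag3 was not without that filter (0.059), and neither Lag3 (0.069) nor Il12rb2 (0.053) was with a pseudocount of 100. Not called were Rora (-0.43, adjusted p = 0.053), Icos (0.27), Prdm1 (0.20), Ets1 (-0.16), Nfil3 (0.12), Il10 (0.05) and Ets2 (0.00).

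Late, 9 of the 18 tested members of the Tr1 list, Il10 included, rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 1.4e-09, and 2.7e-06 with an estimated correlation). Il10 itself, the cytokine gene by which Tr1 cells are known, rose by 0.64 ± 0.07 (adjusted p = 2.4e-08) from a mean intensity of 10.1, below every array median, to 35.7, within their range. Besides Il21 (3.14), higher genes included Nfil3 (1.68 ± 0.09, adjusted p = 2.9e-16), a transcription factor that can act on Il10, Il12rb2 (1.29 ± 0.09), Prdm1 (16.5, below every array median, to 121; 1.28 ± 0.20), which encodes Blimp-1, and Gzmb (1.20 ± 0.17). Ahr (0.90 ± 0.11), Lag3 (0.77 ± 0.11) and Batf (0.50 ± 0.11) rose as well, and Ets2 fell by 0.37 ± 0.10, a call lost without 72 h (-0.31, adjusted p = 0.059) and without arrays of suffix d (-0.45, 0.058). The Ahr value came from the brighter of 2 probe sets, the other of which read 12.0 in ctrl and 12.8 in IL27 (0.03). Not called were Ets1 (0.39, adjusted p = 0.074), Irf1 (-0.36, 0.073, and 0.032 without the 12 h control array), Rora (0.24), Bhlhe40 (-0.24), Stat3 (0.23), Irf4 (0.20), Egr2 (0.19) and Icos (0.07). Maf and Havcr2 did not pass the filter on low values, the single Maf probe set reading 12.8 in ctrl and 13.6 in IL27 late, and Ikzf3 was not analysed here.

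The effect of IL-27 itself differed between the early and late windows for 508 of 7163 genes (249 with a higher late difference, 259 with a lower one), tested as a contrast of both windows in one model. Among Tr1 regulators, Nfil3 (late minus early 1.62 ± 0.17, adjusted p = 9.0e-08), Il12rb2 (1.27 ± 0.16), Il21 (2.65 ± 0.35), Il10 (0.62 ± 0.14), Lag3 (0.73 ± 0.20) and Gzmb (1.01 ± 0.32) gained. Irf1 (-1.40 ± 0.26), Batf (-1.13 ± 0.21) and Irf4 (-0.94 ± 0.28) lost. The list had 6 up and 3 down of 18 (6 and 4 adjusted over the list alone; camera adjusted p = 0.026, and 0.054 with an estimated correlation). The interferon response list changed most, with 26 of 28 members lower late (28 adjusted over the list alone), a median of -1.37 and a camera adjusted p of 1.3e-40 (0.0027 with an estimated correlation). The RNA sensor Ifih1 (-2.02 ± 0.22), Cxcl10 (-2.64 ± 0.29) and Rsad2 (-0.82 ± 0.09) had the smallest adjusted p. Treg genes had 3 lower of 11 (5 adjusted over the list alone) and a median of -0.51 (camera adjusted p = 0.00036, and 0.013 with an estimated correlation) and cytotoxic genes of 1.01 (0.0012, and 0.0077 with an estimated correlation). Further lists were called only at the preset correlation: MHC class I (median -0.41, adjusted p = 0.16 with an estimated correlation), cholesterol biosynthesis (-0.31, 0.16), glycolysis and hypoxia (0.27, 0.24), unfolded protein response (0.12, 0.24) and MHC class II (-0.47, 0.18). Without the 12 h control array, 730 genes differed between the windows, 508 of them shared, and the early and late windows had 236 and 1693 calls. Without 2 h the count of genes was 158, and without the arrays of suffix d it was 261. In the calls of single windows, the higher genes of the early and middle windows shared 56 genes against 6.17 for independent lists, those of the middle and late windows 105 against 30.1, and those of the early and late windows 22 against 11.2. The lower genes shared 8 against 2.22, 170 against 40.9 and 8 against 3.71, in the same order, and 18 genes were called in opposite directions early and late, among them Cd274, Cd28, Ifih1 and Psme1.

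At single times, the first calls were those of 37 genes at 1 h, among them Cxcl10, Batf, Irf1, Irf4, Socs1 and Iigp1. Of other genes, picked after their values were seen, Tbx21 and Socs3 were first called at 2 h, Gzmb at 8 h, Il21 at 16 h and Il12rb2 at 20 h. Nfil3 and Plac8 followed at 30 h, Il10 at 48 h and Prdm1 at 54 h. Il10 stood at 10.4 in ctrl and 58.7 in IL27 at 48 h (log2 difference 1.10 ± 0.25, adjusted p = 0.015), with 42 h just short of the threshold (0.65 ± 0.17, adjusted p = 0.057). The test took its spread from the duplicated times with 16 residual degrees of freedom, and a time with 1 array per arm was assumed to vary like them, so a first call also depends on the number of arrays at that time. limma called 0 genes at 0.5 h, with 38 at an unadjusted p under 0.05 where chance gives 358.15, so that 0 does not show that no gene differed. At 7 of the 18 times, this one included, the number at an unadjusted p under 0.05 lay below chance. There were 215 calls at 2 h, 103 at 16 h, 334 at 54 h, 891 at 72 h and 3143 at 12 h. In all, 3900 of 7163 genes were called at 1 or more times, and 1277 without the 12 h control array.

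**Figure D3:**
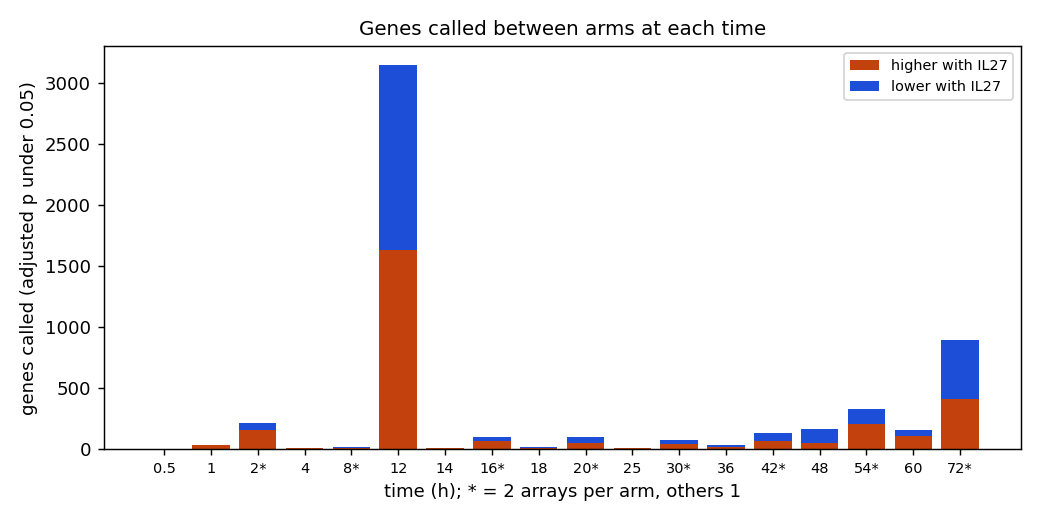
Number of genes called (limma adjusted p under 0.05) between arms at each HT_MG-430A time in hours, higher with IL27 in orange and lower in blue, with stars at times that had 2 arrays per arm. The bar at 12 h (3143 genes) rests on the control array that stood apart, and the next highest is 72 h with 891.

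Control cells without IL-27 changed far more over the same hours, which sets the background for the differences above. From the early to the late window Ube2c rose by 5.68 ± 0.31 (limma adjusted p = 3.6e-14; 5 early and 12 late arrays). Ccna2 rose by 5.25 ± 0.40, Cdk1 by 5.06 ± 0.46, Pclaf by 4.92 ± 0.44, Rrm2 by 4.77 ± 0.50 and Mki67 by 4.75 ± 0.32, all genes of dividing cells. Gzmb (5.29 ± 0.63) and Socs2 (4.74 ± 0.38) rose with them. Klf2 (-5.24 ± 0.40) and S1pr1 (-3.97 ± 0.32), which govern the exit of naive T cells from lymph nodes, and the IL-7 receptor gene Il7r (-4.04 ± 0.60) fell. Also lower were Ifi209 (-4.21 ± 0.33), Vps37b (-4.09 ± 0.37), Rrad (-3.65 ± 0.19), Hsd11b1 (-3.57 ± 0.27) and Smad7 (-3.53 ± 0.22), an inhibitor of TGF-β signalling. In all 4816 of 6961 genes were called (2608 higher, 2208 lower), and 5108 without the 12 h control array (2774 higher, 2334 lower). Cell cycle genes rose in 32 of 33 cases (32 adjusted over the list alone; camera adjusted p = 3.0e-11), cholesterol biosynthesis genes in 15 of 16 (15; 1.4e-05) and glycolysis and hypoxia genes in 15 of 17 (15; 8.5e-05). Each had an adjusted p of 0.40 with an estimated correlation. Naive and memory genes fell in 10 of 12 cases and rose in 1 (the same adjusted over the list alone; camera adjusted p = 0.00041, and 0.23 with an estimated correlation). T-cell activation genes fell in 15 and rose in 5 of 22 (the same adjusted over the list alone; 0.020, and 0.49 with an estimated correlation). Interferon genes fell in 13 and rose in 4 of 26 (the same adjusted over the list alone; 0.045, and 0.60 with an estimated correlation). The other lists were not called (camera adjusted p from 0.069 to 0.99). Among markers of other cells, H2-Aa changed by -2.98 ± 0.26, Lyz2 by -1.09 ± 0.16 and Mpeg1 by -0.69 ± 0.08.

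On the Mouse430A_2 arrays, with 1 array per arm at 4, 16 and 48 h, the question was whether genes named above move the same way in a separate set of arrays. Tbx21 differed by 2.42 at 4 h and 3.74 at 16 h, Il21 by 5.22 and Plac8 by 4.77 at 48 h, and Tnfsf11 by -4.48 at 48 h. Il10 stayed far below the array median there, and its difference at 48 h was 0.07. Of the 16 genes named for their size in each window, the other sign was seen for Scd2 early (0.01), for none in the middle window and for Igfbp7 late (0.20). Of the called Tr1 regulators not among these, Irf4 early (-0.15, 1 of 3) and Ets2 late (0.10, 1 of 9) had the other sign, and none of 11 in the middle window. Among further called members of the lists the other sign was seen for 4 of 33 early, which were Bcl6 (0.05), Mcm4 (-0.30), Psme1 (-0.09) and Oasl1 (-0.22). In the middle window it was 1 of 54, Il13 (0.11), and late 3 of 83, Gbp2 (-0.02), Pkm (-0.14) and Slc16a3 (-0.0015). Over the 3 pairs, limma called 0 of 6055 genes, with 436 at an unadjusted p under 0.05 where chance gives 302.75, and the smallest adjusted p was 0.099, for Stap1, Utf1 and Itm2a. Those 3 genes were picked after their values were seen. The fit held 1 IL-27 effect for all 3 times, so a change of the effect with time counted as spread. Tbx21, which stood at -0.13 at 48 h, is an example picked after its values were seen. With 2 of the 3 times, and fewer residual degrees of freedom, 87 genes were called without 16 h, 211 without 48 h and 0 without 4 h. Camera called the STAT3 and SOCS list (adjusted p = 1.1e-12) and the Tr1 list (2.0e-08) at the preset correlation, and each had an adjusted p of 0.20 with an estimated correlation, the lowest of any list. The lists of interferon, glycolysis, cholesterol, unfolded protein, cytotoxic, cell cycle, Th1 and MHC class I genes were also called only at the preset correlation (adjusted p from 0.20 to 0.65 when estimated). Of the genes called on HT_MG-430A, 715 of 764 from the middle window had the same sign at 16 h (93.6%, exact binomial 95% interval 91.6 to 95.2). So had 1228 of 1325 from the late window at 48 h (92.7%, 91.1 to 94.0), against 131 of 166 from the early window at 4 h (78.9%, 71.9 to 84.9). Across all 7163 genes, which are not independent replicates, 64.9%, 70.7% and 60.8% had the same sign and Pearson's r was 0.75, 0.81 and 0.44. The intervals treat genes as independent and are too narrow for genes that move together.

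**Figure D4:**
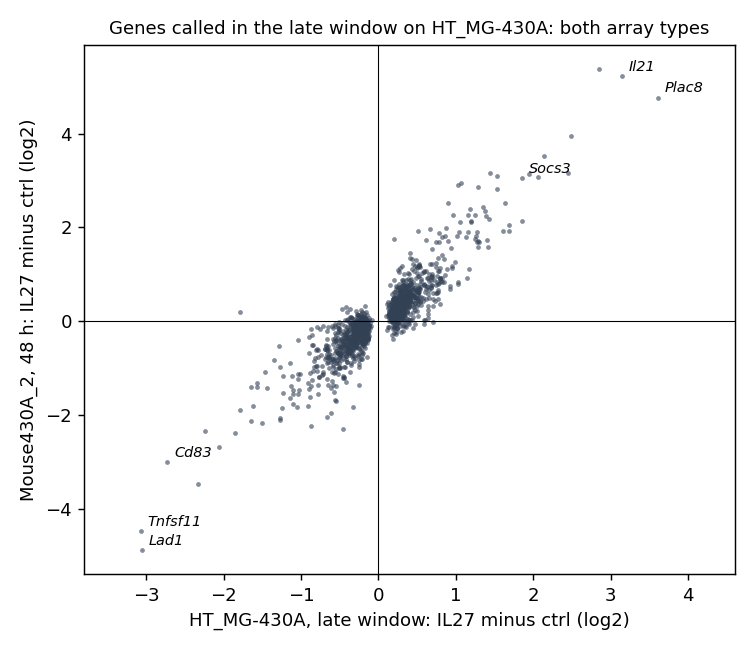
Log2 difference between arms of the 1325 genes called in the late window on HT_MG-430A (horizontal axis) and of the same genes on Mouse430A_2 at 48 h (vertical axis), 1 point per gene with a few named. Of these genes 92.7% lie in the quadrants where both signs are the same, and Pearson's r across them was 0.91.

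GFPP and GFPN, which the labels do not expand, were compared at 48 h by values alone, since each had 1 array. Il21 read 2143 and 2172 in them, near IL27 (2218) and not ctrl (28.4) at 48 h. Socs3 did likewise (5018 and 4933, against 5756 and 665), while Ahr lay between the arms (116 and 188, against 362 and 37.0). The array nearest to IL27 at 48 h was GFPN (r = 0.991). These genes were picked after their values were seen. Among 6612 genes 8 were at least 2-fold higher in GFPP and 2 at least 2-fold lower, 10 in all against 5 with a pseudocount of 100. Lgals3, which encodes galectin-3, read 2531 in GFPP and 897 in GFPN (log2 ratio 1.46). Next came Emp1 (1.24), the chemokine Ccl5 (1.20), Ifng (1.15), which encodes interferon-γ, Klrd1 (1.14), Phxr4 (1.14), Prf1 (1.12), Prdm1 (573 against 267; 1.02), the chemokine Ccl3 (0.91) and Glrx (0.83). Lower in GFPP were Clec2d (-1.40), Vapb (-1.10), Pdlim1, Kif11 and Igfbp4 (each -0.84), Id3 (-0.81), Il6ra (-0.80), and Retreg3, Stk4 and Ms4a4b (each -0.68). Il10 read 22.2 in GFPP and 20.6 in GFPN, both under their array medians of 76.3 and 74.3. Further Tr1 members were Nfil3 (0.36), Gzmb (0.30), Lag3 (0.29), Icos (0.23), Irf1 (0.17), Bhlhe40 (0.07), Rora (0.04) and Il12rb2 (0.02), then Ets1 (0.00), Batf (0.00), Il21 (-0.02), Irf4 (-0.03), Stat3 (-0.12), Ets2 (-0.19), Egr2 (-0.36) and Ahr (-0.58), with Maf (-0.08) and Havcr2 (0.12) below the array medians as well. The list's median lay at percentile 71.1 of 10000 random lists matched on mean expression. Set against such lists, the cytotoxic genes (median 0.36, 8 of 8 higher in GFPP) and the Th1 genes (0.31, 10 of 12) lay at percentile 100. Treg genes lay at 99.85, co-inhibitory and co-stimulatory receptors at 99.4, STAT3 and SOCS genes at 98.7 and cell cycle genes at 94.4. Glycolysis genes lay at 91.1, interferon genes at 90.4, MHC class I genes at 86.8, T-cell activation genes at 81.1, cholesterol genes at 52.02 and unfolded protein response genes at 27.7. Naive and memory genes (median -0.14, 1 of 10 higher) lay at 0.01 and myeloid and dendritic markers at 1.54. These percentiles describe this pair of arrays only.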

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

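Tests of the 12 h control array against another array of its table, of interferon members above the array median and of the others, of other cells in the early IL-27 cultures, of other splits on Mouse430A_2 and of exchanges within pairs of one suffix were chosen after the result was seen, and the rule of the test on low late interferon signals was made stricter then. The IL-27 effect differed between the early and late windows for 508 genes by the test of the late minus early difference, and the same test singled out 9 lists and 34 named genes. Of the lists, the medians were 0.46 for Tr1 regulators, -1.37 for interferon genes, -0.41 for MHC class I, -0.51 for Treg, 1.01 for cytotoxic, 0.27 for glycolysis, -0.31 for cholesterol, 0.12 for unfolded protein response and -0.47 for MHC class II genes. With an estimated correlation the interferon, Treg and cytotoxic lists were still called and the other 6 were not (adjusted p from 0.054 to 0.24). Genes with a larger or less negative IL-27 difference late were Plac8 (3.44), Ctla2a (2.97), Il21 (2.65), Mt2 (2.48), Mt1 (2.34), Selp (2.12), Serpinb5 (2.05), Nfil3 (1.62), Il12rb2 (1.27), Gzmb (1.01), Cd28 (0.99), Scd2 (0.83), Lag3 (0.73), Il10 (0.62), Sit1 (0.59) and Hvcn1 (0.56). Those with a smaller or more negative one were Iigp1 (-3.33), Ifi205 (-2.96), Cxcl10 (-2.64), Lad1 (-2.61), Tnfsf11 (-2.47), Cd83 (-2.45), Rtp4 (-2.13), Ifit1 (-2.13), Zbp1 (-2.12), Csf2 (-2.11), Gbp10 (-2.01), Eomes (-1.94), Socs1 (-1.90), Igfbp7 (-1.78), Fasl (-1.53), Irf1 (-1.40), Batf (-1.13) and Irf4 (-0.94). Groups of one arm and time held 1 or 2 arrays, so no group of 4 to 10 could be tested for an outlying array, and arrays of a window, which differ in time, were not tested as a group.

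Interferon genes were higher with IL-27 early and not late. Of the 25 members called early, 15 lay above the array median late in the IL27 arm (60%, exact binomial 95% interval 38.7 to 78.9), a share that does not decide on late signals too low to show a difference. Over the 15 members above the median in both arms the early median was 1.29 and the late one -0.19 (SE 0.15), which argues against low signals for these. Of the other 10, Isg20 was called lower late (66.5 in ctrl and 45.2 in IL27, -0.57 ± 0.17), so its signal was not too low to show a difference. For the rest, with late control readings from 12.0 (Oasl2) to 30.0 (Ifit1), low late signals cannot be told apart from a loss of the effect. The control level of each of the 10 was lower late than early (median -0.94, SE 0.33). Only where such a late reading is mostly background could a rise by the same factor lie under the floor, and how much is background was not measured. In 5 of the 10 a rise did show early at times with the control below the array median (median 2.59, SE 0.62). All 10 were picked for an early call, so these rises do not show that a late one would be seen. A larger share of other cells in the early IL-27 cultures than in ctrl is argued against by their markers, whose highest list median was 0.06. Other cells present alike in both arms cannot be addressed by this difference. Some markers had signal in both arms early, such as Cd74 at 273 in ctrl and 262 in IL27. A change of the response with time, which the design names, stays open and was not tested apart from this contrast.

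The 12 h control array stood apart. Its deviations from neighbouring control arrays had a correlation of 0.056 between the 2 brightest probe sets of a gene (2464 genes), against 0.218 to 0.856 on the other control arrays. In addition, 276 genes lay 4-fold or more below their neighbours against 2 above, with Coro1a at -5.99. Deviations that differ between probe sets of one gene are consistent with array or RNA quality as a candidate explanation. Other cells are argued against by a highest marker median of 0.1393 (erythroid), and an exchange with another array of the table by a highest correlation of 0.8525. No biological explanation besides other cells was tested.

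Cytotoxic genes were higher with IL-27 late, at a median of 1.20. CD8 T cell and NK markers had a median late difference of 9.6e-05, but only 1 of the 5 lay above the array median in either arm, so a small share of such cells cannot be told apart from expression by the CD4 T cells. The 1 marker with signal, Cd8b1, fell by 0.62. The other CD8 marker, Cd8a, read 11.8 in ctrl and 11.6 in IL27, below the median in both arms. The fall of Cd8b1 alone therefore does not decide on a share of CD8 T cells. The NK marker Klrc1, also below the median in both arms, was higher (0.17 ± 0.06, adjusted p = 0.043 without the filter on low values). Klrd1, a cytotoxic list member for an NK receptor chain, was higher too (0.63 ± 0.16, adjusted p = 0.0030). The other NK markers, Ncr1 (0.0057) and Klra8 (9.6e-05), lay below the median in both arms and were not called. The rises of Klrc1 and Klrd1 therefore do not decide on a share of NK cells. The effect of IL-27 on the CD4 T cells themselves, which the design names, stays open.

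Among other splits of the arrays, 1 split, the real one, gave as many calls in each of 5 comparisons. The middle window had 764 calls against at most 178 in other splits and the late 1325 against 775. A chance division of these arrays into arms can be excluded for both only if arrays of different times are independent. The labels do not say so. A difference between cultures, each sampled over time, would favour the real split as well. Late minus early had 508 against 320 and control cells 4816 against 3941. Their other splits mixed early with late times, and neighbouring times of a course resemble each other, so these splits cannot exclude chance. The early window had 166 against 80 over 24 splits. That excludes chance only if arrays are independent and the suffix d does not pair the arms. If it does, exchanges of the arms within pairs leave 16 early splits, too few for a share under 0.05, with 166 calls against 80. In the middle and late windows 1 of 100 such exchanges, the real one, gave as many, with 764 against 646 and 1325 against 457. Chance can be excluded there with pairs too, again only if pairs of different times are independent. On Mouse430A_2 the splits are too few, 4, for a share under 0.05, with 0 calls in the real one and 11 as the highest other.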

How the results depend on the processing

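Leaving out the 12 h control array, leaving out the 48 h arrays in the list tests and taking gene names from each array type's own table were chosen after the result was seen; the other settings were planned. Some counts of calls moved by over 1.5 times, and the cause was not tested. The middle window had 1609 calls instead of 764 as a mean of single-time contrasts, and without arrays of suffix d the early window had 57 instead of 166 and late minus early 261 instead of 508. Ranges over left-out times include counts that moved less. Leaving out each time in turn gave 9 (without 2 h) to 192 calls early, 439 (without 16 h) to 957 in the middle window, with 462 without 20 h, 883 (without 54 h) to 1339 late, 158 (without 2 h) to 533 for late minus early and, on Mouse430A_2, 0 to 211, with 87 without 16 h. In control cells, where 4 early times and no late one were left out, it gave 4208 to 4866. Without the 12 h control array the single times called 1277 genes instead of 3900. With a pseudocount of 100 GFPP and GFPN differed 2-fold for 5 genes instead of 10. With an estimated correlation 11 lists were called instead of 21. Smaller moves were 26 lists with fry, 21 without the 48 h arrays, and 90.7% of middle calls with the same sign on both array types without a filter, outside the interval of the 93.6% with it. Of 87 gene results, single alternatives ended a call 33 times and single left-out times 38 times, 16 of these without 2 h, and list calls ended 19 times, 10 of them with an estimated correlation. Igfbp7 late went to -0.07 with a pseudocount of 1, and the middle Th2 median to 0.03 among genes above the median mean value (adjusted p = 0.44). None of these 87 gene results changed sign; other called genes were only counted. Scd2 early went from -0.78 to -0.32 and Ahr in the middle window from 0.45 to 0.21 with the mean of all probe sets. Whether the suffix d pairs the arms stays open. The correlation between arms of d minus other arrays was 0.501 to 0.749 at 6 of 8 times, 0.177 at 72 h and -0.048 at 30 h. A comparison with only the other arm's arrays of the same time gave a further hint of a pairing from the values. Of 32 arrays, 28 were closer to the one of their own suffix. Among all arrays, the nearest one was of the own arm from 12 h on. The main models did not take the suffix as a pairing. Any shift that arrays of one suffix share between arms therefore lies in their spread, also at single times. With a replicate block for that suffix, calls were 223, 1060, 1654 and 714 for early, middle, late and late minus early, and 5445 at single times.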

Other observations

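All observations here were chosen after the result was seen, from single times of the HT_MG-430A arrays and 1 pair of the Mouse430A_2 arrays, and were not tested beyond those times. The Gzmb difference was 2.37 at 36 h (706 in ctrl, 3785 in IL27; adjusted p = 0.00089) and 0.48 at 48 h, 0.54 at 54 h, 0.62 at 60 h and 0.21 at 72 h (7595 and 8895), none of these called (adjusted p from 0.28 to 0.69). The Mouse430A_2 pair at 48 h differed more, by 2.12 (4002 and 17446), so the small difference at 48 h may not hold. The HT_MG-430A control array of 48 h correlated least with its nearest array after the 12 h one. Its deviations from neighbouring control arrays were alike between probe sets of a gene, however (r = 0.856). That cannot show whether the sample itself was like its neighbours. Prdm1 stood at 54.4 in ctrl and 327 in IL27 at 1 h (2.05 ± 0.55, adjusted p = 0.16, not called), at 18.3 and 19.6 at 8 h, and at 23.6 and 299 at 72 h (2.41 ± 0.39, adjusted p = 0.00022). Tbx21 differed by 3.52 at 16 h (137 and 1837; adjusted p = 9.1e-06) and by 0.23 at 48 h, 0.02 at 54 h (511 and 520), 0.38 at 60 h and 0.46 at 72 h, none of these called (adjusted p from 0.50 to 0.99). Whether these differences themselves differ between times was not tested at single times.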
